A study of Mus musculus with 24 samples.

How the data were processed

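Liver RNA of 24 male C57BL/6J mice was measured by RNA sequencing, 1 library per mouse, in 4 groups of 6. Per the labels' protocols, mice were acclimated over 5 days to diets of up to 4% ethanol, then took a 5% ethanol liquid diet for 10 days and a binge gavage of 5 g/kg ethanol, or were pair-fed an ethanol-free control. Within each diet, mice received corn oil vehicle or 0.2 mg/kg PCB126, a dioxin-like polychlorinated biphenyl that binds the aryl hydrocarbon receptor (AhR). Libraries came from the TruSeq Stranded mRNA kit.

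The deposited table holds raw counts per Ensembl gene, made by the authors with HTSeq 0.10.0 after FastQC 0.10.1 on genome build GRCm39, per the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so counts of genes that overlap on opposite strands were not separated further. The table lists 55414 gene identifiers, all columns were whole numbers and each was matched to 1 mouse. Symbols came from a GENCODE mouse annotation of an earlier build, matched by identifier: 52081 identifiers had a symbol and held 99.8% of all counts. Genomic positions are not given, because that annotation and the counts use different builds.

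Total counts ranged from 5.39 to 103 M per library (M, 1e6 counts), with a median of 35.0 M, and 26849 genes had no count in any library. A count of 0 in a library was read as at most 3 counts, which limits counting error only. The 60 pairs of libraries within groups had Spearman correlations from 0.970 to 0.994 across genes. Their lowest chi-square per degree of freedom was 11.4, so that no pair differed by counting noise alone as repeated sequencing of 1 library would.

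Genes with enough counts were kept with filterByExpr (minimum count 10), which left 14484, and library totals were scaled with TMM. Counts per 1e6 (CPM) are TMM-scaled, and log2 CPM used a prior count of 2. All 24 libraries entered 1 edgeR quasi-likelihood fit of 4 group means with robust estimation and 20 residual degrees of freedom. The 5 comparisons were the PCB126 effect in each diet, the ethanol effect with each agent, and the interaction, which is the PCB126 effect in ethanol-fed mice minus that in pair-fed mice. Tests were two-sided F-tests, p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05, and the standard error (SE) of a log2 fold change was its size divided by the square root of F. Values across mice are means ± SD, and n is the number of mice per group. Genes said to have risen or fallen lay on that side of the other group's mean in 6 of 6 mice unless the text gives fewer.

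Gene lists were fixed for AhR targets, NRF2 and glutathione, CAR and PXR targets, ethanol metabolism, lipogenesis, PPAR-alpha and fatty acid oxidation, and lipid uptake, droplets and export. Further lists covered cholesterol synthesis, bile acids, glucose and insulin, iron, zinc with copper and manganese, selenium, acute phase, cytokines and chemokines, endoplasmic reticulum stress with the integrated stress response, 1-carbon and methionine metabolism, circadian clock, male-biased and female-biased liver genes, coagulation and complement, and the cell cycle. Marker lists covered pericentral and periportal hepatocytes, macrophages, neutrophils, lymphocytes, stellate cells and matrix, endothelium, cholangiocytes, pancreatic acinar cells, adipocytes, erythroid cells and the mitochondrial genome. Of these 34 lists, 33 had enough tested members for the limma camera test on voom values (preset correlation 0.01, adjusted over the lists of a comparison), which was repeated with an estimated correlation. Members past the threshold were counted with the adjustment over all genes and adjusted over the list alone. Unless a sentence says otherwise, a count of a list's members that rose or fell uses the adjustment over all genes.

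Genes were named by this rule: in each of the 4 simple comparisons, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 1 CPM, leaving out predicted models; up to 4 members per list with the smallest p; and 11 genes whatever their result (Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Cyp2e1, Mt1, Mt2, Hamp and Cd36). The interaction names at most 10 genes. Groups, lists, the main tests, the naming rule and most alternatives were chosen before the data were examined, and later choices are named where their results are given. Single values per library, such as the share of albumin counts, were compared with two-sided exact permutation tests.

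The alternatives were DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in 6 libraries, the DESeq2 test, limma-voom with sample quality weights, only the 2 groups compared, a replicate block, no robust estimation, and leaving out each library. Every library thinned to 5.39 M counts, and the 3 libraries under 11 M left out, were added after seeing the data. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Some genes that the naming rule took are not reported here by name, and counts include them.

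The fit was tested on simulated data of about this depth that may vary less than these. It recovered 57.6% of genes changed 1.5-fold in a PCB126 comparison within either diet, 84.6% (pair-fed) and 73.1% (ethanol-fed) of those changed 2-fold, and 98.4% and 93.8% of those changed 4-fold. For an interaction these shares were 27.3%, 58.2% and 84.4%. Of all calls, 4.32%, 5.16% and 7.50% fell on unchanged genes in the pair-fed, ethanol-fed and interaction settings.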

Results

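RNA sequencing counts were compared across 24 livers in a design that crosses diet (pair-fed or ethanol-fed) with agent (corn oil vehicle or 0.2 mg/kg PCB126), with n = 6 mice in each of the 4 groups. Per the labels' protocols and the series title, the question is how PCB126 changes the hepatic transcriptome in alcohol-associated liver disease. Total counts per library, in M (1e6 counts), were 51.7 ± 31.1 in pair-fed vehicle, 31.4 ± 10.7 in pair-fed PCB126, 23.5 ± 12.8 in ethanol-fed vehicle and 43.5 ± 32.5 in ethanol-fed PCB126 mice (SD, n = 6). The ethanol-fed and pair-fed vehicle groups differed in depth by a two-sided exact permutation test on log2 totals (p = 0.0498, n = 6), but not after adjustment over the 20 tests of library measures (adjusted p = 0.142).

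Cyp1a1, the classical AhR target, separated the agents in both diets. In pair-fed mice its level was 3084 to 4371 CPM with PCB126 and 0.654 to 3.11 CPM with vehicle. In ethanol-fed mice it was 1698 to 4235 CPM against 1.08 to 1.57 CPM. Each difference had a two-sided exact permutation p of 0.00216 (n = 6), the smallest that 6 against 6 mice allow. Albumin took a smaller share of counts with PCB126: 8.13% ± 0.614 against 9.32% ± 0.377 in pair-fed mice and 7.39% ± 1.13 against 9.48% ± 0.853 in ethanol-fed mice (SD, n = 6, two-sided exact permutation p = 0.00649 and 0.00433, each 0.0325 after adjustment over 20 tests). Diet separated the libraries along the first principal component of log2 CPM, which held 36.9% of the variance, and ethanol-fed PCB126 mice 1, 5 and 4 had the highest values of their group on the second (62.0, 38.4 and 20.3).

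**Figure D1:**
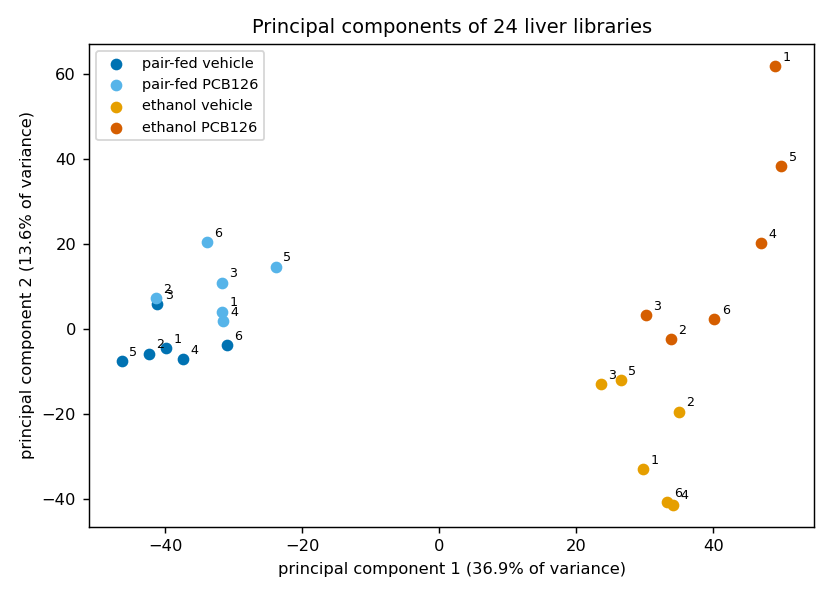
Principal components 1 (36.9% of variance) and 2 (13.6%) of log2 CPM, 1 point per library, coloured by group (n = 6 per group). Pair-fed and ethanol-fed libraries part along component 1, and ethanol-fed PCB126 mice 1, 5 and 4 lie highest of their group on component 2.

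In pair-fed mice, PCB126 raised AhR targets. Cyp1a1 (ENSMUSG00000032315) rose from 1.38 ± 0.968 to 3851 ± 523 CPM (SD, n = 6), a log2 fold change of 11.38 ± 0.42 (SE). Cyp1a2 (ENSMUSG00000032310) rose by 4.80 ± 0.20 and Cyp1b1 (ENSMUSG00000024087) by 5.48 ± 0.62. At a mean of 1 CPM or more over the 24 libraries, the 6 largest rises also included Nptx1 (7.72 ± 0.74) and Cyfip2 (3.76 ± 0.31). The largest such falls were Cyp2c40 (-3.15 ± 0.42), the nuclear receptor Nr4a1 (-2.29 ± 0.46) and Dio3os (-1.51 ± 0.39). Foxq1 (-1.43 ± 0.35), Phlda1 (-1.11 ± 0.24) and Flvcr2 (-1.07 ± 0.22) followed. Dio3os lost its call in 9 of the 24 fits that left out 1 library, with the highest edgeR adjusted p (0.092) without PCB126 mouse 3, and Foxq1 in 6 of 24 (0.0652 without vehicle mouse 5).

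Of the 19 tested AhR targets, 13 rose in pair-fed mice with PCB126 (16 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.28. This list was called by camera (adjusted p = 2.17e-32) and kept its call with an estimated correlation (adjusted p = 0.000481). Beside the cytochromes, the AhR repressor Ahrr rose by 3.88 ± 0.58, Htatip2 by 2.40 ± 0.13, the lysosomal transporter Slc46a3 by 2.27 ± 0.15 and the quinone reductase Nqo1 by 1.28 ± 0.21. Tiparp, another classical target, did not pass (0.18 ± 0.24, edgeR adjusted p = 0.807), and its sign turned without PCB126 mouse 5 (-0.19).

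Of the 27 NRF2 and glutathione genes, 6 rose (8 adjusted over the list alone), among them the transferase Gsta4 (0.67 ± 0.13), the efflux pump Abcc3 (0.78 ± 0.15) and sulfiredoxin Srxn1 (0.58 ± 0.12). Camera called this list (adjusted p = 1.93e-06), with an adjusted p = 0.652 with an estimated correlation. Of the 19 pericentral hepatocyte genes, 5 rose (7 adjusted over the list alone), including Cyp2a5 (1.70 ± 0.26), Slc1a4 (1.21 ± 0.21) and Rhbg (1.11 ± 0.20). Camera called it (adjusted p = 0.000612), with an adjusted p = 0.652 with an estimated correlation. In the lipid uptake, droplet and export list, 4 of 29 genes rose (adjusted over the list alone, also 4). They were the fatty acid transporter Cd36 (1.06 ± 0.21), Vldlr (1.49 ± 0.35), Lpl (1.12 ± 0.27) and Mogat1 (0.96 ± 0.25). Vldlr was higher than the vehicle mean in 5 of 6 mice. Cd36 kept its call without each library in turn, while the highest edgeR adjusted p was 0.0632 for Vldlr (without vehicle mouse 3), 0.0702 for Lpl (without PCB126 mouse 2) and 0.114 for Mogat1 (without PCB126 mouse 3). Without vehicle mouse 3 or 5 the NRF2 and pericentral counts were both 3, and the NRF2 count was also 3 without PCB126 mouse 4 or 6. The lipid uptake count was 2 without any 1 pair-fed library other than vehicle mouse 4 and PCB126 mouse 5, 2 with a replicate block or thinned libraries and 1 with no filter, and the pericentral count was 3 with no filter.

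Smaller parts of other lists passed in pair-fed mice with PCB126. Among CAR and PXR targets, 2 of 25 rose, Cyp2b10 (2.25 ± 0.46) and Cyp2c29 (1.05 ± 0.24), and adjusted over the list alone the count was also 2. Selenbp1 rose (0.74 ± 0.13) with Selenok (0.49 ± 0.13), 2 of 23 selenium genes (2 rose and 1 fell adjusted over the list alone). Ucp2 rose (1.16 ± 0.17) as 1 of 37 PPAR-alpha and fatty acid oxidation genes, and 1 of 22 stellate cell and matrix genes rose. Of 15 female-biased genes, Cyp2c40 and Cyp2c69 (-3.77 ± 0.52) fell (3 adjusted over the list alone). Also 1 of 10 cholangiocyte genes fell, and Cela1 (-0.76 ± 0.14), the 1 tested pancreatic acinar gene, fell. Without vehicle mouse 3 the edgeR adjusted p was 0.0558 for Cyp2c29 and 0.118 for Selenok, and without vehicle mouse 5 no stellate cell or cholangiocyte gene passed.

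The remaining 23 lists had no member past the threshold in pair-fed mice by edgeR. Of their 450 members, counted once per list, 43 had an unadjusted p under 0.05 and DESeq2 called 8. These lists were ethanol metabolism, lipogenesis, cholesterol synthesis, bile acids, glucose and insulin, iron, zinc with copper and manganese, acute phase, cytokines, the stress response, 1-carbon metabolism, circadian clock, male-biased genes, coagulation, cell cycle, periportal hepatocytes, macrophages, neutrophils, lymphocytes, endothelium, adipocytes, erythroid cells and the mitochondrial genome. Adjusted over the list alone, 5 of 9 neutrophil genes rose and 1 gene each fell among bile acid and glucose genes. Camera called neutrophils up (adjusted p = 0.0229; 0.752 with an estimated correlation). It called lipogenesis, glucose, circadian, periportal, endothelial and erythroid genes down, with adjusted p = 0.00266, 0.0271, 0.0143, 0.0133, 0.0268 and 0.0268. With an estimated correlation these became adjusted p = 0.652, 0.799, 0.652, 0.799, 0.799 and 0.752. The medians and means of iron and stellate cell genes were above 0 where camera's direction was down. Mt1 and Mt2, the metal-binding metallothioneins, had log2 fold changes of 0.65 ± 0.56 and 0.87 ± 0.67 (edgeR adjusted p = 0.657 and 0.611). Neither Cyp2e1 (0.23 ± 0.14, adjusted p = 0.49) nor the iron hormone Hamp (0.30 ± 0.53, adjusted p = 0.857) passed.

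In all, edgeR called 360 of 14484 genes for PCB126 in pair-fed mice, 284 up and 76 down, and 79 of them changed at least 2-fold (67 up, 12 down). The count moved to 140 up and 69 down with no filter on low counts, 564 with DESeq2 (67.6% up, against 78.9% up in edgeR), 1093 with limma-voom weights and 179 with thinned libraries (added after seeing the data), and to 163 without vehicle mouse 3, 184 up and 32 down without vehicle mouse 5 and 227 without PCB126 mouse 3. Of 36 genes that the naming rule took and edgeR called, 10 lost the call without some library (among them Dio3os, Foxq1, Gstm1, Cyp2c29, Vldlr, Lpl, Mogat1 and Selenok), and reads that the close copies Cyp2c40 and Cyp2c69 share were not separated.

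In ethanol-fed mice, PCB126 raised AhR targets and parts of the macrophage, cell cycle and cytokine lists. Cyp1a1 rose from 1.37 ± 0.212 to 2864 ± 1049 CPM (SD, n = 6), a log2 fold change of 11.01 ± 0.42 (SE). Nptx1 rose by 5.52 ± 0.74, Cyp1b1 by 4.71 ± 0.65, Cyfip2 by 4.02 ± 0.32, Cyp1a2 by 3.84 ± 0.20 and the macrophage glycoprotein Gpnmb by 3.65 ± 0.84. At 1 CPM or more, Cfd (complement factor D, made mainly in fat), Hsd3b5 (-3.18 ± 0.90) and Serpina1e (-2.22 ± 0.59) fell most. Plin4 (-1.97 ± 0.29), Cyp4a14 (-1.63 ± 0.46) and Nr4a1 (-1.49 ± 0.43) followed. Cfd had no count in any of the 6 PCB126 livers, so it was at least 75.1-fold lower, set against a floor of 3 counts over the group. This limit was 24.8-fold without vehicle mouse 1, which held 92 of the 122 vehicle counts, and 48.7-fold without PCB126 mouse 5. The call of Cfd was lost without vehicle mouse 1 (edgeR adjusted p = 0.0822) or PCB126 mouse 5 (0.0680). The adjusted p without PCB126 mouse 5 was also 0.155 for Hsd3b5, 0.083 for Serpina1e and 0.11 for Cyp4a14, which lost their calls in 7, 6 and 12 of the 24 fits that left out 1 library, and Nr4a1 lost its call in 16 (0.155 without vehicle mouse 3).

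Of 19 AhR targets, 16 rose and 1 fell in ethanol-fed mice (18 and 1 adjusted over the list alone; camera adjusted p = 1.27e-31), and the call held with an estimated correlation (adjusted p = 0.000559). Slc46a3 rose by 2.67 ± 0.15, Htatip2 by 1.64 ± 0.13, Nqo1 by 1.59 ± 0.20 and Ahrr by 4.58 ± 0.85, while Tiparp (0.62 ± 0.25) did not pass (edgeR adjusted p = 0.146). Of 27 NRF2 and glutathione genes, 9 rose (17 rose and 1 fell adjusted over the list alone), including the cystine transporter Slc7a11 (4.16 ± 0.61), Pgd (0.76 ± 0.14) and Srxn1 (0.71 ± 0.12). Camera called the list (adjusted p = 2.07e-10; adjusted p = 0.335 with an estimated correlation), and with only the 2 groups compared 4 genes rose.

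Macrophage markers formed the second group: 12 of 22 rose (18 adjusted over the list alone), with a median log2 fold change of 1.05 and camera adjusted p = 1.78e-11. With an estimated correlation the adjusted p was 0.354. The lysosomal glycoprotein Cd68 rose by 1.28 ± 0.27, the complement gene C1qa by 0.96 ± 0.25 and the antibody receptor Fcgr1 by 1.74 ± 0.46. The mean log2 CPM of the list was 3.03 ± 0.775 with PCB126 and 1.84 ± 0.571 with vehicle (SD, n = 6, two-sided exact permutation p = 0.00433, adjusted 0.0247 over 40 tests). Endothelial markers had means of 4.88 ± 0.141 and 4.82 ± 0.229 (two-sided exact permutation p = 0.626, n = 6), and of 15 endothelial genes none passed by edgeR or DESeq2 (1 was at an unadjusted p under 0.05). The rise was uneven across mice. Cd68 was at 28.6, 14.6 and 22.6 CPM (not TMM-scaled) in PCB126 mice 1, 4 and 5 and at 8.67, 6.62 and 7.49 in mice 2, 3 and 6, against 2.91 to 6.79 in vehicle mice. Mice 1, 4 and 5 were also the 3 with the highest second component and the lowest albumin share of their group (5.55%, 7.14% and 7.24%). The count of macrophage genes depended on single libraries: it was 2 without vehicle mouse 1, vehicle mouse 4, PCB126 mouse 1 or PCB126 mouse 5, and 5 without vehicle mouse 2 or 5. It was also 2 with no filter on low counts or with limma-voom weights, 1 with a replicate block, 4 with thinned libraries, and 0 with only the 2 groups compared or with the 3 libraries under 11 M counts left out, against 16 by DESeq2. Without PCB126 mouse 1 the edgeR adjusted p was 0.0747 for C1qa and 0.0804 for Fcgr1.

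Of 25 cell cycle genes, 11 rose (15 adjusted over the list alone), with camera adjusted p = 6.41e-08 (0.194 with an estimated correlation). The proliferation marker Mki67 rose by 2.39 ± 0.36, highest in PCB126 mouse 1 and lowest in mouse 4. Topoisomerase Top2a rose by 2.17 ± 0.40, Cdk1 by 2.08 ± 0.40 and Foxm1 by 1.85 ± 0.36. The list's mean log2 CPM was 1.26 ± 0.504 against 0.393 ± 0.191 (SD, n = 6, two-sided exact permutation p = 0.00216, adjusted 0.0144 over 40 tests). The count was 6 without PCB126 mouse 5, 6 with the filter of 1 CPM in 6 libraries or with only the 2 groups compared, 7 with limma-voom weights or without the 3 shallow libraries, and 1 with thinned libraries. Thinning left 11 of the 25 members tested, with a median log2 fold change of 0.21 against 0.28 in the main fit over the same 11 and 0.92 over all 25.

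Cytokine and matrix genes rose in smaller numbers. Of 18 cytokine and chemokine genes, 5 rose (10 adjusted over the list alone; camera adjusted p = 0.000395; adjusted p = 0.427 with an estimated correlation), among them the chemokines Cxcl10 (2.77 ± 0.53) and Ccl2 (2.71 ± 0.66) and the inflammasome sensor Nlrp3 (1.40 ± 0.34). Of 22 stellate cell and matrix genes, 4 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000316; adjusted p = 0.427 with an estimated correlation), namely the collagens Col3a1 (1.53 ± 0.33), Col1a1 (1.35 ± 0.34) and Col1a2 (0.91 ± 0.23) and the matrix protein Sparc (0.47 ± 0.11). Of 17 lymphocyte genes, Ighm rose (0.95 ± 0.23; 1 also adjusted over the list alone), with camera adjusted p = 0.000482 and adjusted p = 0.415 with an estimated correlation. Without PCB126 mouse 5 the edgeR adjusted p was 0.0652 for Ccl2, 0.0606 for Col1a1 and 0.0625 for Col1a2. The cytokine count was 2 without vehicle mouse 1 or PCB126 mouse 5, 9 without PCB126 mouse 2 or by DESeq2, 3 with limma-voom weights, and 1 with only the 2 groups compared, thinned libraries or the 3 shallow libraries left out. The matrix count was 2 without vehicle mouse 4 or PCB126 mouse 5 or with no filter, 1 with limma-voom weights and 0 with only the 2 groups compared. By mean log2 CPM per mouse, the cytokine list was higher by 0.83, the matrix list by 0.37 and the lymphocyte list by 0.77 (two-sided exact permutation p = 0.0152, 0.0541 and 0.0195, n = 6), and none passed over 40 tests (adjusted 0.0606, 0.120 and 0.0708).

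**Figure D2:**
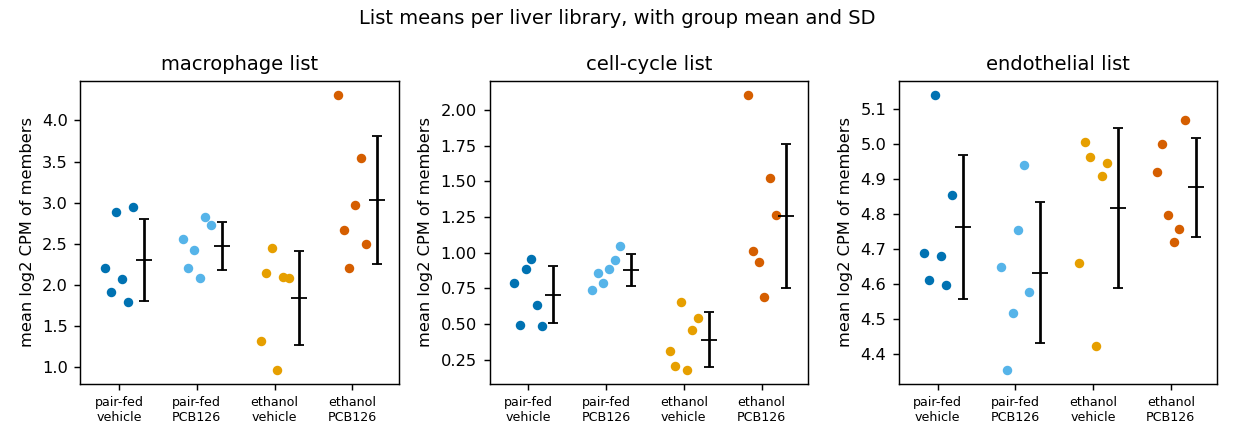
Mean log2 CPM of the macrophage, cell cycle and endothelial lists, 1 point per library by group, with the group mean and SD (n = 6). In ethanol-fed mice the macrophage mean was 3.03 with PCB126 and 1.84 with vehicle, the cell cycle mean 1.26 and 0.393, and the endothelial mean 4.88 and 4.82.

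Small parts of several hepatocyte lists fell in ethanol-fed mice with PCB126, where the albumin share was also lower. Of 26 acute phase genes, 3 fell and 1 rose (11 and 2 adjusted over the list alone), including haptoglobin Hp (-0.81 ± 0.20), Serpina3m (-0.81 ± 0.23) and Itih3 (-0.96 ± 0.28, lower in 5 of 6 mice) against Cd14 (1.39 ± 0.33). Of 23 male-biased genes, 4 fell (5 adjusted over the list alone), such as the major urinary protein Mup3 (-0.99 ± 0.22). Of 22 lipogenic genes, 3 fell (5 fell and 1 rose adjusted over the list alone), namely Fads2 (-0.78 ± 0.15), Fads1 (-0.61 ± 0.12) and Agpat2 (-0.62 ± 0.13). Of 37 PPAR-alpha genes, 2 fell (Cyp4a14 and Cpt1a, -0.41 ± 0.12) and Ucp2 rose (0.90 ± 0.18). Of 29 lipid uptake genes, Plin4 and Apoc3 (-0.45 ± 0.13) fell and Lpl rose (1.52 ± 0.28). Adjusted over the list alone, 8 fell and 1 rose in the former, and 2 fell and 1 rose in the latter. Alb itself fell by -0.51 ± 0.15 as 1 of 21 periportal genes (also 1 adjusted over the list alone). Camera called these lists down with adjusted p = 4.29e-05 (acute phase), 0.0162 (male-biased), 0.00783 (lipogenesis), 2.06e-06 (PPAR-alpha), 0.000285 (lipid uptake) and 0.0105 (periportal). They became adjusted p = 0.427, 0.548, 0.427, 0.427, 0.0631 and 0.548 with an estimated correlation. Among genes of these lists, the highest edgeR adjusted p without 1 library was 0.0589 for Hp (without vehicle mouse 1), 0.0869 for Serpina3m (without PCB126 mouse 1) and 0.0929 for Alb (without vehicle mouse 4). Without PCB126 mouse 5 it was 0.116 for Itih3, 0.0555 for Cd14, 0.127 for Cpt1a and 0.111 for Apoc3. Counts that fell also moved without 1 library. For acute phase genes the 3 became 0 (vehicle mouse 1 or 4, PCB126 mouse 5), 1 (vehicle mouse 2 or 6, PCB126 mouse 1 or 4), 5 (vehicle mouse 5), 6 (pair-fed vehicle mouse 6) or 8 (PCB126 mouse 2). For male-biased genes the 4 became 2 (vehicle mouse 1, PCB126 mouse 1 or 4) or 1 (vehicle mouse 3, 4 or 5, PCB126 mouse 5). For PPAR-alpha genes the 2 became 14 without PCB126 mouse 2, 0 without vehicle mouse 1, 2, 3 or 6, PCB126 mouse 1 or 5, pair-fed vehicle mouse 1 or 2 or pair-fed PCB126 mouse 6, and 1 without PCB126 mouse 3 or 6, pair-fed vehicle mouse 3 or 4 or pair-fed PCB126 mouse 1, 2, 3 or 4. Between settings the acute phase count ranged from 0 (no filter, replicate block or the 3 shallow libraries left out) to 9 (limma-voom weights), the male-biased count from 0 (only the 2 groups compared) to 5, and the PPAR-alpha count from 0 (no filter, only the 2 groups compared, thinned or without the 3 shallow libraries) to 7 (DESeq2). The acute phase mean per mouse differed by -0.51 (two-sided exact permutation p = 0.0714, n = 6, adjusted 0.143 over 40 tests).

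Coagulation and complement (1 of 27 fell, Hc, -0.43 ± 0.13; 6 adjusted over the list alone), glucose and insulin (2 of 20 fell, Foxo1, -0.46 ± 0.12, and Igf1, -0.33 ± 0.09; 3 adjusted over the list alone) and 1-carbon metabolism (2 of 25 fell, Cbs, -0.63 ± 0.12, and Bhmt, -0.97 ± 0.28; 4 adjusted over the list alone) were also called down. Their camera adjusted p-values were 4.3e-07, 0.0121 and 0.0115, and each had an adjusted p = 0.427 with an estimated correlation. Single members passed in lists that camera did not call. The heme transporter Slc48a1 rose (0.43 ± 0.10) and Hp fell among 26 iron genes, Slc39a11 rose (0.32 ± 0.09) among 29 zinc, copper and manganese genes, and Selenbp1 rose (1.36 ± 0.13) among 23 selenium genes. Psat1, a serine synthesis enzyme, rose (0.88 ± 0.17) among 26 stress response genes, Srebf2 fell (-0.41 ± 0.11) among 25 cholesterol genes, Amacr fell (-0.40 ± 0.11) among 23 bile acid genes and Slc1a4 rose (0.76 ± 0.19) among 19 pericentral genes. Among 25 CAR and PXR targets Cyp2c55 rose (0.84 ± 0.25) and Cyp3a11 fell (-1.36 ± 0.20). Of 15 female-biased genes, Cyp2a4 (3.33 ± 0.45) and Fmo1 (0.39 ± 0.12) rose and Cyp2c69 (-2.85 ± 0.69) fell. Adjusted over the list alone the female-biased counts were 3 up and 3 down, selenium had 1 up and 1 down, and the other lists without a camera call had the same counts as over all genes. Cela1 (-0.69 ± 0.15, pancreatic acinar), Alas2 (-0.90 ± 0.13, 1 of 6 erythroid) and Cfd (1 of 5 adipocyte, 2 adjusted over the list alone) fell. Without PCB126 mouse 5 the edgeR adjusted p was 0.11 for Hc, 0.0685 for Foxo1, 0.0999 for Igf1, 0.122 for Bhmt, 0.115 for Amacr, 0.0774 for Slc1a4 (higher in 5 of 6 mice) and 0.057 for Cyp2c69. It was 0.0691 for Slc39a11 and 0.0948 for Fmo1 without vehicle mouse 3, 0.0887 for Srebf2 without vehicle mouse 1 and 0.126 for Cyp2c55 without PCB126 mouse 4.

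The 6 lists without a call by edgeR in ethanol-fed mice given PCB126 were ethanol metabolism, circadian clock, neutrophils, endothelium, cholangiocytes and the mitochondrial genome, where 10 of 74 members had an unadjusted p under 0.05 and DESeq2 called 1. Adjusted over the list alone, 1 cholangiocyte gene rose. Median and camera direction differed in sign for CAR and PXR targets, cholesterol and female-biased genes, and median and mean for cholesterol, stress response, selenium and pericentral genes. Mt1 (-0.97 ± 0.56), Mt2 (-1.27 ± 0.68), Hamp (-0.29 ± 0.53), Cyp2e1 (-0.38 ± 0.14) and Cd36 (0.43 ± 0.21) did not pass (edgeR adjusted p = 0.358, 0.306, 0.821, 0.126 and 0.236).

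For PCB126 in ethanol-fed mice, edgeR called 782 genes, 530 up and 252 down, and 323 changed at least 2-fold (300 up, 23 down). The count moved to 521 with no filter, 1189 with DESeq2, 491 with limma-voom weights, 270 with only the 2 groups compared, 400 with thinned libraries and 281 without the 3 libraries under 11 M counts (both added after seeing the data), and to 403, 481, 440, 333 and 1244 without vehicle mouse 1, vehicle mouse 4 or PCB126 mouse 1, 5 or 2. Of 69 named genes with a call, 30 lost it without some library, and Gpnmb lost it with limma-voom weights, a replicate block, only the 2 groups compared or the 3 shallow libraries left out.

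The PCB126 effects in both diets shared 81 genes that rose and 17 that fell, against 10.4 and 1.32 expected if the calls were independent, and these comparisons use no library in common. No gene was called in opposite directions. Of the 360 genes called in pair-fed mice, 316 (87.8%) had the same sign in ethanol-fed mice, and of the 782 called in ethanol-fed mice 647 (82.7%) had the same sign in pair-fed mice.

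**Figure D3:**
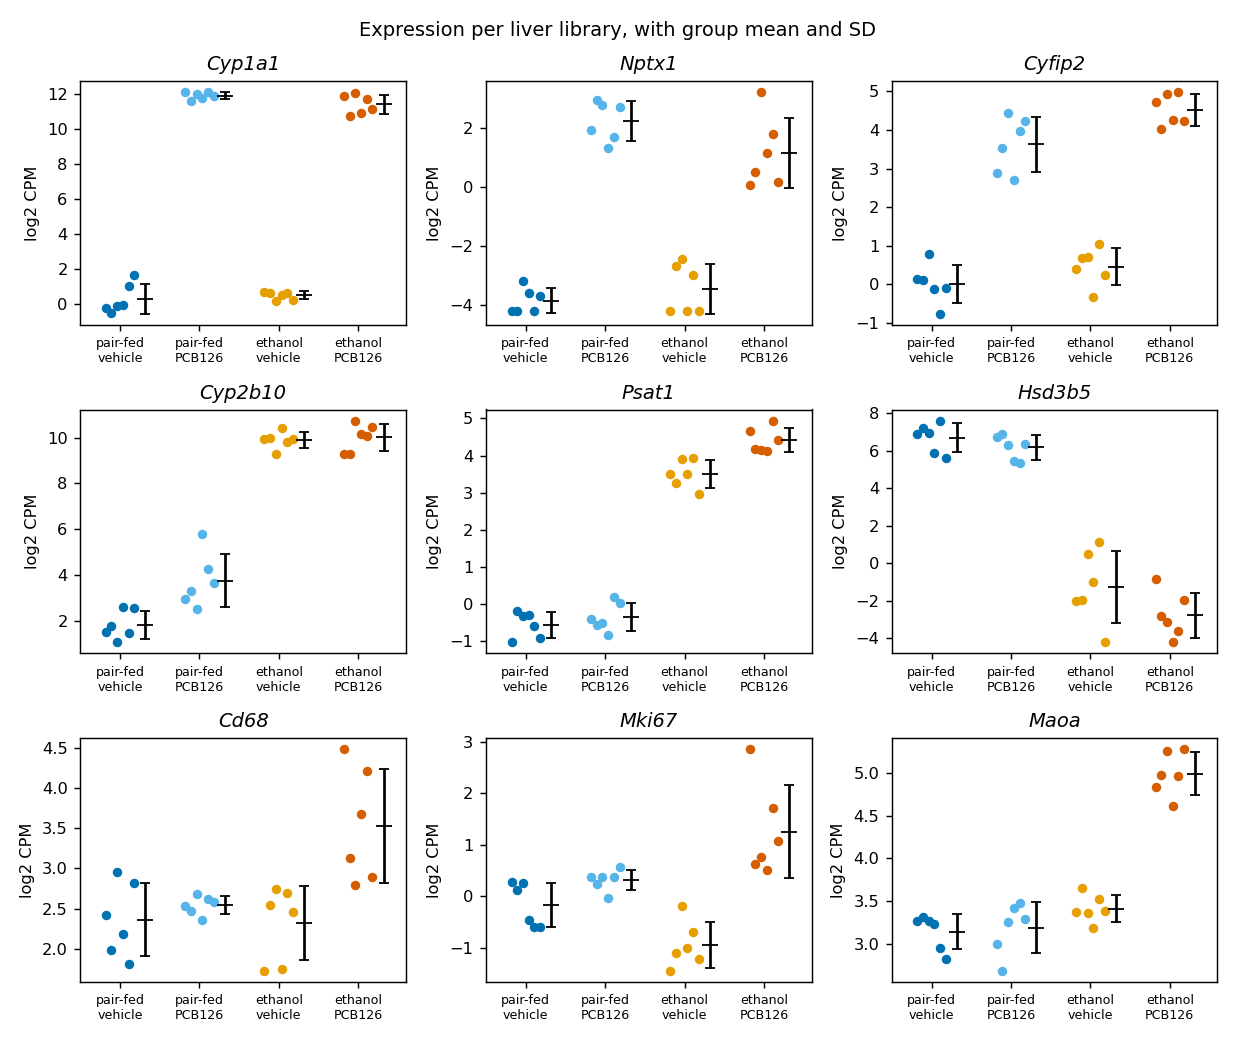
Log2 CPM of Cyp1a1, Nptx1, Cyfip2, Cyp2b10, Psat1, Hsd3b5, Cd68, Mki67 and Maoa, 1 point per library in the 4 groups, with mean and SD (n = 6). Cyp1a1 separates PCB126 from vehicle in both diets, Cyp2b10, Psat1 and Hsd3b5 separate the diets, and Maoa is highest in ethanol-fed PCB126 mice.

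In vehicle mice, ethanol raised some NRF2, CAR and stress response genes and lowered some male-biased, lipogenic, oxidation and bile acid genes. Cyp2b10 (ENSMUSG00000030483), the classical target of the receptor CAR, rose from 3.80 ± 1.72 to 973 ± 233 CPM (SD, n = 6), a log2 fold change of 7.97 ± 0.58 (SE). Among the 6 largest rises were also Cyp2a4 (6.90 ± 0.65), the clock factor Npas2 (6.47 ± 0.84), the glutathione transferase Gsta1 (6.29 ± 0.46) and Cyp2b9 (5.88 ± 1.16). Vmn2r3, a vomeronasal receptor gene, had no count in pair-fed vehicle mice and was at least 261-fold higher with ethanol (floor of 3 counts over the group), and at least 169.9-fold without ethanol-fed mouse 5, which held 168 of its counts. The largest falls were Hsd3b5, a male-biased steroid dehydrogenase, from 117 ± 55.4 to 0.721 ± 0.839 CPM (-7.02 ± 0.55), Ugt2b38 (-4.75 ± 0.87), Clec2h (-4.70 ± 0.67), Ppp1r3g (-4.63 ± 0.80), Chrna4 (-4.50 ± 0.74) and Mup21 (-4.09 ± 0.44).

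Of 27 NRF2 and glutathione genes, 17 rose with ethanol in vehicle mice (18 adjusted over the list alone), including Abcc4 (4.54 ± 0.32), Cbr3 (4.39 ± 0.31), Gstm1 (2.67 ± 0.19) and Srxn1 (2.08 ± 0.13). Of 25 CAR and PXR targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with Cyp2c29 (2.81 ± 0.25) and Cyp2c55 (2.51 ± 0.28) up and the heme synthesis enzyme Alas1 down (-1.91 ± 0.18). Of 26 stress response genes, 11 rose (14 adjusted over the list alone), with Nupr1 (4.97 ± 0.44), Trib3 (4.77 ± 0.40), Psat1 (4.22 ± 0.21) and Ddit3 (3.88 ± 0.37), and the count was 18 with limma-voom weights and 17 with only the 2 groups compared. Of 19 AhR targets, 7 rose and 2 fell (the same counts adjusted over the list alone), with Gsta2 (3.35 ± 0.30), Nqo1 (2.21 ± 0.21) and Cyp1a2 (1.25 ± 0.18) up. Cyp1a1 (-0.06 ± 0.34), Cyp1b1 (0.41 ± 0.76), Ahrr (-1.80 ± 1.06) and Tiparp (0.25 ± 0.25) did not pass (edgeR adjusted p = 0.918, 0.71, 0.192 and 0.454), and the sign of Cyp1a1 turned without pair-fed mouse 5 (0.03), pair-fed mouse 6 (0.43) or ethanol-fed mouse 3 (0.03). Camera called these 4 lists up with adjusted p = 1.63e-09, 0.0014, 2.95e-06 and 0.036, in the order named. With an estimated correlation these became adjusted p = 0.389, 0.47, 0.389 and 0.587.

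In vehicle mice ethanol lowered some lipogenic, oxidation, sterol and glucose genes. Of 22 lipogenic genes, 15 fell (16 adjusted over the list alone), including Acly (-1.82 ± 0.23) and the desaturases Fads2 (-1.38 ± 0.15) and Fads1 (-0.75 ± 0.12). Of 37 PPAR-alpha and fatty acid oxidation genes, 19 fell and 4 rose (22 and 4 adjusted over the list alone), with Fabp1 (-1.73 ± 0.15) and Ppara (-1.18 ± 0.17) down and the thioesterase Acot2 up (2.66 ± 0.20). Of 25 cholesterol genes, 12 fell (13 adjusted over the list alone), among them Stard4 (-1.57 ± 0.19) and Insig1 (-1.30 ± 0.19). Of 23 bile acid genes, 9 fell and 1 rose (the same counts adjusted over the list alone), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.97 ± 0.42), and the uptake transporter Slco1a1 (-1.92 ± 0.29). Of 20 glucose and insulin genes, 8 fell (8 adjusted over the list alone), including glycogen synthase Gys2 (-1.40 ± 0.12) and G6pc (-1.26 ± 0.22). Camera called these 5 lists down with adjusted p = 3.84e-06, 3.73e-05, 5.13e-05, 0.0225 and 0.00256. With an estimated correlation they had adjusted p = 0.389, 0.508, 0.508, 0.556 and 0.417. The cholesterol count was 7 without pair-fed mouse 2 or ethanol-fed mouse 3 or 6.

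Other metabolic lists were mixed and not called by camera. Of 14 ethanol metabolism genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone), with the alcohol dehydrogenase Adh4 (-1.36 ± 0.14), Acss2 (-0.86 ± 0.15) and Cyp2e1 (-0.77 ± 0.15) down. Of 29 lipid uptake, droplet and export genes, 9 rose and 6 fell (10 and 6 adjusted over the list alone), with Vldlr (2.76 ± 0.35), Cd36 (1.12 ± 0.21) and Plin3 (0.87 ± 0.10) up and Fabp2 (-1.35 ± 0.19) down. Of 25 genes of 1-carbon and methionine metabolism, 8 rose and 7 fell (9 and 7 adjusted over the list alone), with Chka (2.88 ± 0.35) and Mthfd2 (2.69 ± 0.23) up and Mtr (-0.93 ± 0.13) down. Of 19 pericentral genes, 6 rose and 4 fell (6 and 6 adjusted over the list alone), with Cyp2a5 (3.09 ± 0.27) and Rhbg (2.06 ± 0.20) up. Of 21 periportal genes, 4 rose and 2 fell (3 and 1 adjusted over the list alone), with Sdsl up (0.96 ± 0.22) and Etnppl down (-1.37 ± 0.36). The 5 ethanol metabolism genes that rose became 3 without pair-fed mouse 2 or 6, 2 without pair-fed mouse 3 or ethanol-fed mouse 1 or 4, and 1 without pair-fed mouse 5 or with no filter on low counts. The 2 periportal genes that fell became 1 without pair-fed mouse 5 or 6 or ethanol-fed mouse 1, 2, 3, 4 or 6. With limma-voom weights 7 periportal genes rose and 7 pericentral genes fell. Median and mean differed in sign for 1-carbon and pericentral genes.

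Metal-related genes responded in both directions to ethanol in vehicle mice. The metallothioneins Mt1 (2.31 ± 0.58) and Mt2 (2.45 ± 0.70) rose, as did the zinc transporter Slc39a4 (0.80 ± 0.15), while the zinc transporter Slc39a5 (-1.46 ± 0.35) and the copper chaperone Ccs (-0.65 ± 0.12) fell. In all, 6 of 29 zinc, copper and manganese genes rose and 5 fell (the same counts adjusted over the list alone; 3 fell with thinned libraries). Of 26 iron genes, 10 rose and 7 fell (10 and 7 also adjusted over the list alone), with the heme transporter Slc48a1 (0.94 ± 0.10), ferritin Fth1 (0.83 ± 0.11) and Hfe2 (0.68 ± 0.10) up and Aco1 down (-0.46 ± 0.08). Hamp, the iron hormone hepcidin, did not pass (-0.68 ± 0.53, edgeR adjusted p = 0.332). Of 23 selenium genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone), with the glutathione peroxidase Gpx3 up (1.23 ± 0.17) and Selenoo (-0.84 ± 0.10) and Txnrd3 (-1.01 ± 0.16) down. None of these 3 lists was called by camera (adjusted p = 0.794, 0.429 and 0.134).

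Sex-biased liver genes moved together: 19 of 23 male-biased genes fell with ethanol in vehicle mice (also 19 adjusted over the list alone), with a median of -1.63, including Nudt7 (-2.35 ± 0.15) and Cyp4a12b (-2.11 ± 0.22). Of 15 female-biased genes, 8 rose and 2 fell (8 and 3 adjusted over the list alone), with Cyp2a22 (5.65 ± 0.39), Tox (1.40 ± 0.22) and Cyp39a1 (1.32 ± 0.21) up. Camera adjusted p-values were 1.13e-11 down and 0.036 up, and with an estimated correlation the adjusted p = 0.32 and 0.556.

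Neutrophil genes rose and lymphocyte genes fell with ethanol in vehicle mice, and parts of other immune lists moved. Of 26 acute phase genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Orm3 (2.91 ± 0.46), Il1rn (1.64 ± 0.27) and Lbp (0.92 ± 0.18) up and Saa4 down (-1.55 ± 0.23). Of 9 neutrophil genes, 7 rose (also 7 adjusted over the list alone), including Retnlg (2.18 ± 0.42), S100a9 (2.06 ± 0.53) and Hdc (1.55 ± 0.22). Of 22 macrophage genes, 3 fell (1 adjusted over the list alone), with the Kupffer cell receptor Timd4 at -0.99 ± 0.28. Of 17 lymphocyte genes, 5 fell (4 adjusted over the list alone), including Ighm (-1.22 ± 0.22) and Cd79b (-1.35 ± 0.38). Camera adjusted p-values were 0.00265, 0.00265, 0.0211 and 0.00245 in this order, and with an estimated correlation the adjusted p = 0.587, 0.417, 0.66 and 0.417. Of 18 cytokine genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone), with Icam1 up (1.49 ± 0.22) and Irf7 down (-1.26 ± 0.32). Of 22 stellate and matrix genes, 9 rose and 1 fell (9 and 3 adjusted over the list alone), with Dcn (0.75 ± 0.13) and Lrat (0.97 ± 0.19) up. Of 25 cell cycle genes, 1 rose and 7 fell (the same adjusted over the list alone), with Mcm5 (-1.47 ± 0.28) and Ccne1 (-1.52 ± 0.29) down. Camera did not call the cytokine, matrix and cell cycle lists, and the cytokine median was below 0 with a mean above it. By mean log2 CPM per mouse, the neutrophil list was higher by 1.31 and the lymphocyte list differed by -0.90 (two-sided exact permutation p = 0.00216 for both, n = 6, adjusted 0.0144 over 40 tests). The acute phase (0.89), macrophage (-0.46), cytokine (-0.04), matrix (0.25) and cell cycle (-0.31) means did not pass (adjusted 0.0722, 0.247, 0.857, 0.0866 and 0.0799). The macrophage count was 1 without pair-fed mouse 3 or 6 or ethanol-fed mouse 1, 4 or 5, and 5 without ethanol-fed PCB126 mouse 1. It was also 1 with no filter, a replicate block or thinned libraries, 5 with DESeq2 or limma-voom weights and 6 without the 3 shallow libraries. The neutrophil count was 3 with the filter of 1 CPM in 6 libraries and 2 with thinned libraries, which left 5 and 3 of the 9 members tested. For lymphocyte genes both settings left 2 of 17 members tested, and both fell. With no filter 8 acute phase genes rose, and with thinned libraries 3 cell cycle genes fell. The lymphocyte count was 3 without ethanol-fed mouse 1, 2 or 4.

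In vehicle mice edgeR called 5044 genes for ethanol, 2714 up and 2330 down, and 1063 changed at least 2-fold (569 up, 494 down). The latter count was 642 with thinned libraries (added after seeing the data), and Clec4f, Mpeg1, Cd4 and Cd79a were the 4 of 135 named genes with a call that lost it without some library. Reads shared between close copies (Cyp2a4 and Cyp2a5, Cyp2b9 and Cyp2b10, Gsta1 and Gsta2, the Mup genes) were not separated.

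In PCB126 mice, ethanol raised most NRF2 and glutathione genes and lowered most male-biased genes. Cyp2a4 rose by 9.27 ± 0.65, Vmn2r3 by 9.08 ± 1.41, the clock factor Npas2 by 6.41 ± 1.06 (in 5 of 6 mice), Ypel4 by 6.22 ± 0.98, Nrg1 by 6.10 ± 0.63 and Gsta1 by 5.95 ± 0.39 (log2 ± SE, n = 6). Cfd was at least 266-fold lower in ethanol-fed mice, where it had no count (floor of 3 counts over the group; 172-fold without ethanol-fed mouse 5), and Hsd3b5 (-9.63 ± 0.67), Ugt2b38 (-4.91 ± 0.84), Slc22a28 (-4.48 ± 0.40), Sema5b (-3.91 ± 0.37) and Mup21 (-3.84 ± 0.43) followed. The AhR targets Cyp1a1 (-0.43 ± 0.27), Cyp1a2 (0.28 ± 0.17), Cyp1b1 (-0.36 ± 0.48) and Ahrr (-1.10 ± 0.48) did not pass (edgeR adjusted p = 0.213, 0.206, 0.589 and 0.0729), and the sign of Cyp1b1 turned without pair-fed mouse 5 (0.03). Tiparp rose (0.70 ± 0.24), with an adjusted p = 0.0769 without ethanol-fed mouse 5.

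Of 7 lists called up in vehicle mice, all but acute phase were in PCB126 mice too. NRF2 and glutathione genes rose in 17 of 27 cases (also 17 adjusted over the list alone), with Abcc4 at 5.33 ± 0.33 and Cbr3 at 5.21 ± 0.32. Likewise 11 of 26 stress response genes rose (11 adjusted over the list alone), with Trib3 at 5.23 ± 0.41 and Psat1 at 4.85 ± 0.21. CAR and PXR targets had 11 up and 2 down of 25 (14 and 3 adjusted over the list alone), with Cyp2b10 at 5.90 ± 0.53 and Alas1 at -2.36 ± 0.19. AhR targets had 9 up and 2 down of 19 (9 and 3 adjusted over the list alone), with Nqo1 at 2.52 ± 0.20. Camera adjusted p-values were 2.71e-10, 0.00404, 0.0174 and 0.0428 for these 4 lists in order, and 0.344, 0.393, 0.445 and 0.474 with an estimated correlation. Without ethanol-fed mouse 3, 4 AhR targets fell.

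Fatty acid oxidation genes fell in 27 of 37 cases and rose in 3 (28 and 3 adjusted over the list alone), with Fabp1 at -1.95 ± 0.16 and Eci2 at -1.13 ± 0.13. Lipogenic genes fell in 12 of 22 and rose in 1 (the same adjusted over the list alone), with Fads2 at -1.73 ± 0.15. Cholesterol genes fell in 12 of 25 (12 adjusted over the list alone) and bile acid genes in 10 of 23 with 3 up (10 and 3 adjusted over the list alone; Cyp7a1 -2.76 ± 0.41). Glucose genes fell in 11 of 20 with 1 up (12 and 1 adjusted over the list alone; Gys2 -1.37 ± 0.12). Ethanol metabolism had 8 of 14 down and 3 up (the same adjusted over the list alone), with Cyp2e1 at -1.39 ± 0.15. Camera called these 6 lists down with adjusted p = 3.63e-11, 2.8e-05, 0.00022, 0.0213, 0.0016 and 0.0313. In the same order, the adjusted p = 0.344, 0.344, 0.42, 0.42, 0.393 and 0.42 with an estimated correlation. Lipid uptake genes had 11 of 29 down and 5 up (11 and 6 adjusted over the list alone; Mgll -1.13 ± 0.14), and 1-carbon genes 8 of 25 down and 4 up (the same adjusted over the list alone; Mthfd2 2.56 ± 0.22). Pericentral genes had 6 of 19 down and 5 up (7 and 5 adjusted over the list alone; Rgn -1.62 ± 0.15), and periportal genes 3 of 21 up and 3 down (3 and 2 adjusted over the list alone; Hsd17b13 0.62 ± 0.09), none called by camera. Without 1 library the ethanol metabolism genes that rose became 1 (pair-fed mouse 2, ethanol-fed mouse 6), the periportal genes that rose 5 or 7 (ethanol-fed mouse 1 or 5) and those that fell 1 (pair-fed mouse 1 or 2, ethanol-fed mouse 2 or 5). With limma-voom weights 6 periportal genes rose, and with these, no filter or only the 2 groups compared 1 fell. Median and mean differed in sign for 1-carbon and pericentral genes.

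Male-biased genes fell in 22 of 23 cases (23 adjusted over the list alone; Cyp4a12b -2.67 ± 0.22) and female-biased genes rose in 9 of 15 (9 adjusted over the list alone; Cyp2a22 4.78 ± 0.38), with camera adjusted p = 2.99e-13 and 0.0027, and adjusted p = 0.217 and 0.393 with an estimated correlation. Among metal genes, Mt1 (0.69 ± 0.56) and Mt2 (0.31 ± 0.67) did not pass in PCB126 mice (edgeR adjusted p = 0.355 and 0.755). Their interaction, tested after these values were seen, did not pass either (Mt1 -1.62 ± 0.79, adjusted p = 0.422; Mt2 -2.15 ± 0.95, adjusted p = 0.385). Of 29 zinc, copper and manganese genes, 3 rose and 9 fell (the same adjusted over the list alone), with Slc39a4 at 1.08 ± 0.15 and Ccs at -0.76 ± 0.12. Of 26 iron genes, 8 rose and 5 fell (8 and 7 adjusted over the list alone), with Slc48a1 at 1.19 ± 0.10 and a median below but a mean above 0. Hamp did not pass (-1.28 ± 0.53, edgeR adjusted p = 0.0641), nor did Cd36 (0.50 ± 0.20, adjusted p = 0.0582). Of 23 selenium genes, 2 rose and 10 fell (3 and 10 adjusted over the list alone; Selenoo -1.06 ± 0.10), with camera adjusted p = 0.0484 and adjusted p = 0.42 with an estimated correlation.

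Matrix genes rose in 12 of 22 cases with ethanol in PCB126 mice (12 adjusted over the list alone; Loxl2 1.43 ± 0.22 and Dcn 0.98 ± 0.13; camera adjusted p = 0.000176; adjusted p = 0.393 with an estimated correlation). Macrophage genes rose in 4 of 22 (4 adjusted over the list alone), with Gpnmb at 3.78 ± 0.82, Trem2 at 2.40 ± 0.48 and Cd68 at 1.12 ± 0.26, and the list was not called (camera adjusted p = 0.118). Cytokine genes had 6 of 18 up and 2 down (the same adjusted over the list alone; Ccl2 3.69 ± 0.69 and Cxcl10 2.58 ± 0.51). Cell cycle genes had 9 of 25 up and 4 down (9 and 4 adjusted over the list alone; Ccnb1 2.65 ± 0.54) and acute phase genes 3 of 26 up and 4 down (3 and 4 adjusted over the list alone; Saa4 -2.37 ± 0.23), and none of these 3 lists was called by camera. Neutrophil genes rose in 3 of 9 (3 adjusted over the list alone; Hdc 1.15 ± 0.22; camera adjusted p = 0.0174; adjusted p = 0.393 with an estimated correlation). Of 17 lymphocyte genes, 2 fell, among them Cd4 (-1.25 ± 0.44). Adjusted over the list alone no lymphocyte gene passed by edgeR, with 5 at an unadjusted p under 0.05 and 5 called by DESeq2. Without 1 library the highest edgeR adjusted p for Cd4 was 0.109 (pair-fed mouse 1). The lymphocyte count was 0 without pair-fed mouse 2, 1 without pair-fed mouse 1 or ethanol-fed mouse 2 or 3, and 4 without pair-fed mouse 5 or ethanol-fed mouse 1. The neutrophil count was 1 without pair-fed mouse 1 or 4 or ethanol-fed mouse 5, the acute phase genes that fell were 2 without pair-fed mouse 3 or 5, and the cell cycle genes that fell were 2 without pair-fed mouse 2 or 3 or ethanol-fed mouse 3 or 6. Of the 9 cell cycle genes that rose, 3 did so with the filter of 1 CPM in 6 libraries (17 of 25 members tested) and 0 with thinned libraries (11 tested), where 1 fell. Those settings gave 2 and 1 macrophage genes and 1 and 1 neutrophil genes. With only the 2 groups compared 2 cell cycle genes and 1 acute phase gene fell, and without the 3 shallow libraries also 1 acute phase gene. By mean log2 CPM per mouse, the matrix list was higher by 0.55 (two-sided exact permutation p = 0.00649, n = 6, adjusted 0.0289 over 40 tests), and the macrophage, cytokine, cell cycle, acute phase, neutrophil and lymphocyte means did not pass (adjusted 0.197, 0.188, 0.181, 0.857, 0.120 and 0.269).

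In PCB126 mice edgeR called 5579 genes for ethanol, 2778 up and 2801 down, and 1189 changed at least 2-fold (728 up, 461 down). The latter count was 725 with thinned libraries (added after seeing the data), and 10 of 131 named genes with a call lost it without some library.

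The ethanol effects with both agents shared 1757 genes that rose and 1677 that fell, against 521 and 451 expected if independent, with 6 in opposite directions and no library in common. Of the 5044 genes called in vehicle mice, 95.7% had the same sign in PCB126 mice, and of the 5579 called in PCB126 mice 94.3% had the same sign in vehicle mice.

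**Figure D4:**
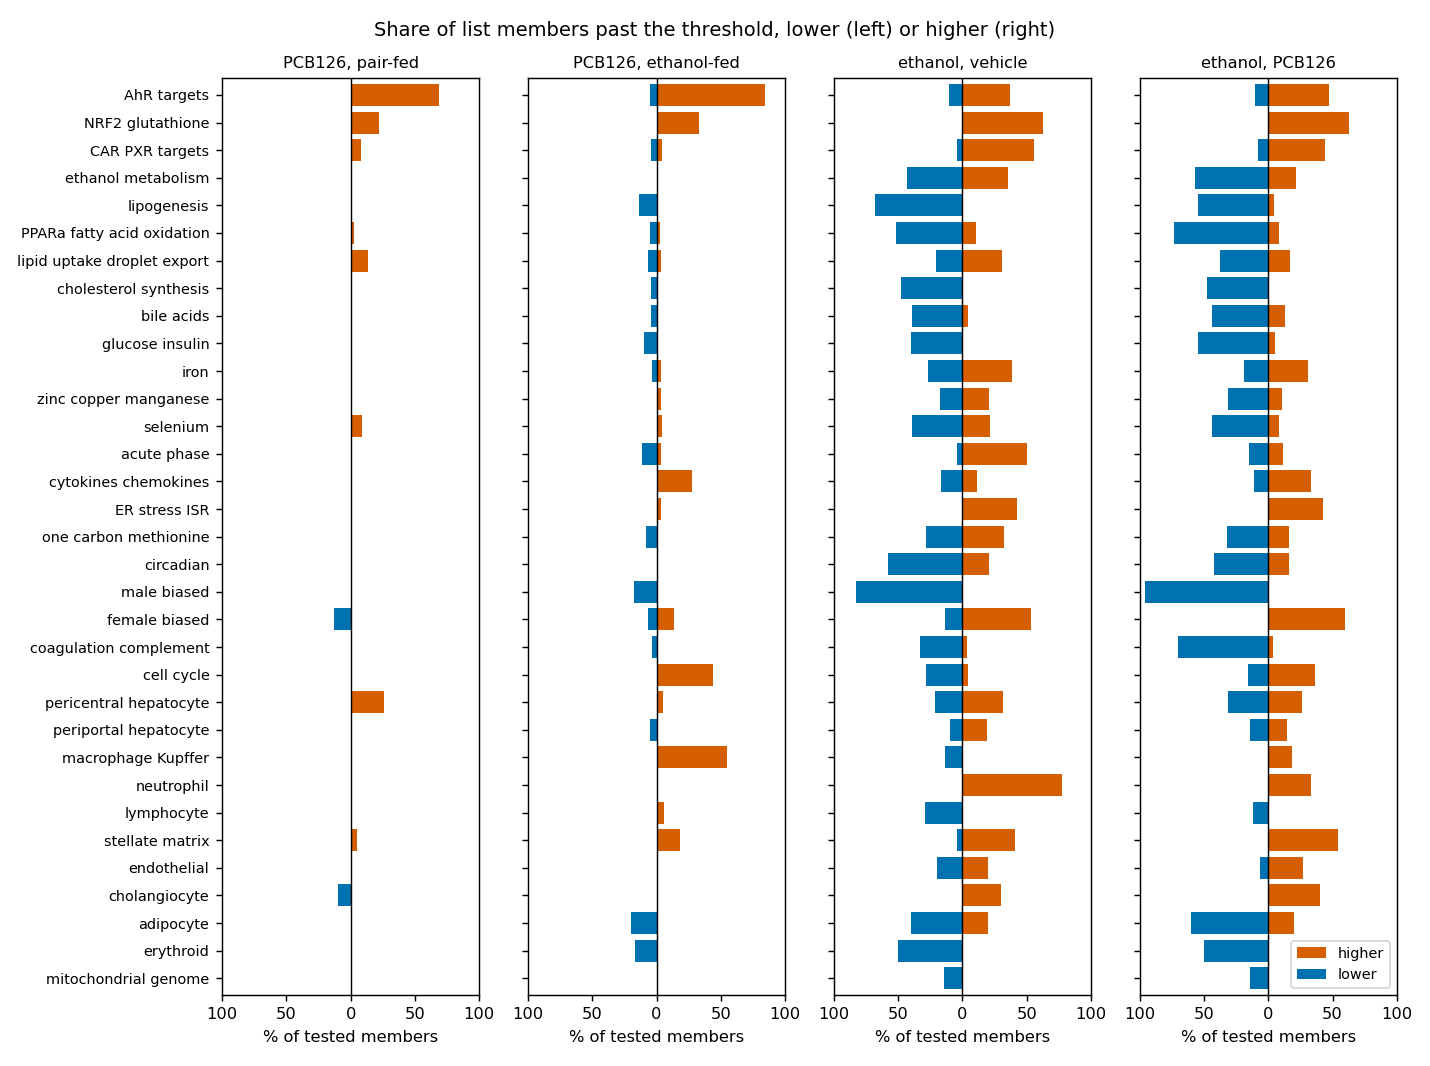
Percent of the tested members of 33 gene lists that rose or fell past the threshold in each of the 4 simple comparisons (edgeR, adjusted over all genes). In vehicle mice 19 of 23 male-biased genes fell with ethanol, and 13 of 19 AhR targets rose with PCB126 in pair-fed mice.

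The PCB126 effect differed between diets for 5 genes (edgeR interaction, 2 up and 3 down). Tuba8, an alpha-tubulin, had means of 1.14, 15.2, 12.8 and 39.6 CPM in pair-fed vehicle, pair-fed PCB126, ethanol-fed vehicle and ethanol-fed PCB126 mice (n = 6). PCB126 raised it by 3.66 (log2) in pair-fed and by 1.61 in ethanol-fed mice, a difference of -2.04 ± 0.23 (SE, edgeR adjusted p = 2.73e-05). Maoa, which encodes monoamine oxidase A, had 8.84, 9.20, 10.6 and 32.1 CPM in the same order, a difference of 1.53 ± 0.18 (adjusted p = 3.83e-05). The aldehyde dehydrogenase Aldh3b1 had 1.16, 1.59, 2.34 and 11.1 CPM, a difference of 1.78 ± 0.28 (adjusted p = 0.00449). Cyp3a11, a target of PXR, had 1191 CPM in pair-fed vehicle, 1292 in pair-fed PCB126, 1155 in ethanol-fed vehicle and 450.4 in ethanol-fed PCB126 mice, a difference of -1.48 ± 0.28 (adjusted p = 0.0453). The glucuronosyltransferase Ugt1a6b had 37.7, 32.3, 38.8 and 18.7 CPM, a difference of -0.82 ± 0.14 (adjusted p = 0.0193), and it shares exons with the other Ugt1a genes.

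Ugt1a6b was 1 of 19 AhR targets and Cyp3a11 1 of 25 CAR and PXR targets to fall by the interaction (4 and 2 adjusted over the list alone). The other 32 lists had no member past the threshold by edgeR, where 117 of 633 members had an unadjusted p under 0.05 and DESeq2 called 5. Adjusted over the list alone, 7 of 25 cell cycle genes were higher, 9 of 26 acute phase genes were lower and 1 higher, and 5 of 19 pericentral genes were lower. Lipid uptake, adipocyte, erythroid and bile acid lists had 2, 2, 1 and 1 lower members by that adjustment, and bile acids, selenium, cytokines and lymphocytes 1 higher member each. Median and mean differed in sign for AhR targets and for bile acid, glucose, female-biased, periportal and erythroid genes. Of the 33 lists, camera called 12 for the interaction (7 up, 5 down). Lipid uptake, droplet and export genes, with a median of -0.25, kept the call with an estimated correlation (adjusted p = 0.0491), and their members with the smallest p, Mogat1 (-1.22 ± 0.37) and Plin4 (-1.33 ± 0.39), did not pass over all genes (edgeR adjusted p = 0.248 and 0.257; named after their values were seen). The macrophage list had a median of 1.01 (camera adjusted p = 1.83e-08; adjusted p = 0.434 with an estimated correlation) and the acute phase list -0.83 (adjusted p = 8.93e-08; adjusted p = 0.434 with an estimated correlation). None of the 22 macrophage genes passed by edgeR or DESeq2, and 13 had an unadjusted p under 0.05.

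Of 14484 genes, 1743 had an unadjusted p under 0.05 for the interaction, and DESeq2 called 53 (36 up, 17 down). Thinned libraries gave 2, and leaving out libraries gave 3 (without pair-fed vehicle mouse 6, pair-fed PCB126 mouse 1 or ethanol-fed vehicle mouse 2), 8 (without ethanol-fed vehicle mouse 3) or 11 (without ethanol-fed PCB126 mouse 2). Tuba8, Maoa and Aldh3b1 kept their calls without each library in turn, Ugt1a6b lost it in 4 of the 24 fits (0.0624 without pair-fed vehicle mouse 6) and Cyp3a11 in 17 (0.127 without pair-fed vehicle mouse 3). Cyp3a11 also lost its call with DESeq2 size factors, with no filter and with the filter of 1 CPM in 6 libraries. Ugt1a6b lost it with limma-voom weights and with a replicate block. Thinned libraries ended the calls of Cyp3a11, Ugt1a6b and Aldh3b1, and leaving out the 3 shallow libraries that of Ugt1a6b (both alternatives added after seeing the data).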

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

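The tests of a lower share of hepatocytes, of female mice and of fat tissue in the pair-fed livers were chosen after the result was seen, and so were the thinning of libraries to equal totals and the medians over members tested in both fits.

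Macrophage and cell cycle genes stood out because they were higher with PCB126 in ethanol-fed mice (12 of 22 and 11 of 25 rose), while the list test of the difference between diets passed with a preset correlation (macrophage median 1.01, adjusted p = 1.83e-08; cell cycle median 0.68, adjusted p = 9.77e-05) and not with an estimated one (adjusted p = 0.434 for both). A lower hepatocyte share would raise other cell types alike. The macrophage list rose 1.14 log2 more than endothelium (two-sided exact permutation p = 0.00649, n = 6). Others ran from -0.28 (erythroid) to 0.77 (lymphocyte), so a lower share stays open. Unequal depth stays open, as thinning keeps expected fold changes (macrophage median 1.02, 4 genes passing). Without the 3 shallow libraries that median was 0.88 with 0 passing. Thinned, 11 of 25 cell cycle genes were tested (median 0.21, 0.28 in the main fit over the same 11 and 0.92 over all). As a hypothesis, PCB126 may add to macrophage content or activation in ethanol-fed livers, but not alike in each: the list's mean log2 CPM was 4.31, 2.97 and 3.54 in PCB126 mice 1, 4 and 5, and 2.67, 2.20 and 2.50 in mice 2, 3 and 6, against 0.960 to 2.45 with vehicle. PCB126 mouse 5 was not shallow (91.9 M). The macrophage count was 2 without vehicle mouse 1 or 4 or PCB126 mouse 1 or 5. Differences between mice in injury or the piece of liver sampled were not tested. None of the 22 members is in another list.

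With ethanol, 19 of 23 male-biased genes fell and 8 of 15 female-biased genes rose (2 fell) in vehicle mice, and 22 and 9 in PCB126 mice, but no list call held with an estimated correlation (adjusted p = 0.32, 0.556, 0.217 and 0.393). Female mice in the ethanol-fed groups are excluded, because the lowest ratio of Ddx3y (on the Y chromosome) to Xist counts over the 12 ethanol-fed libraries was 70. Reads shared between close copies are argued against as the whole explanation: over genes without a close copy, female-biased minus male-biased mean log2 CPM rose by 2.23 with ethanol in vehicle mice (two-sided exact permutation p = 0.00216, n = 6, the smallest possible). In this subset 6 of 7 male-biased genes fell and 4 of 7 female-biased genes rose in vehicle mice, and 7 of 7 and 5 of 7 in PCB126 mice. As a hypothesis, ethanol may weaken the male growth hormone and androgen pattern of the liver, which the design gives as a diet effect and which was not tested by hormone levels.

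Cfd fell with PCB126 in ethanol-fed livers. Fat tissue in ethanol-fed vehicle mouse 1 stays open as an explanation of part of the fall: that library held 24 Adipoq and 92 of 122 Cfd counts, and without it the edgeR adjusted p was 0.0822. The lost call does not show fat as the cause, since 3 other vehicle livers held 30 Cfd counts (15, 9 and 6; mice 2 and 6 had 0) and the PCB126 livers none. Pooled over mice, this was at least 24.8-fold lower against a floor of 3 counts, a limit that covers counting error only and not the spread between mice. The pair-fed livers, in contrast, held 2495 Cfd counts but 7 Adipoq counts over 12 libraries, where the Adipoq to Cfd ratio of that library would give 651 (397 to 1029 from its exact 95% interval), which argues against fat tissue of that ratio as the source of Cfd there (the interval covers counting error only, and the ratio in pair-fed fat was not tested). A change of Cfd in liver cells with diet stays open and was not tested further.

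Among tests of the highest or lowest of 6 libraries against the rest, 14 (6.25% of those run) set 1 apart, and chance alone sets apart about 1 in 20. These were pair-fed vehicle mouse 3 on the second principal component (5.83) and for Hamp (8.60 log2 CPM), pair-fed vehicle mouse 4 for Cyp2e1 (13.52) and ethanol-fed PCB126 mouse 3 for Cyp1a2 (14.19). By mean log2 CPM of a list they were pair-fed vehicle mouse 6 for lipogenesis (7.38), coagulation (9.01) and neutrophils (-0.81), pair-fed PCB126 mouse 4 for CAR and PXR targets (6.19) and lipid uptake (6.52), pair-fed PCB126 mouse 1 for the circadian clock (4.53) and pair-fed PCB126 mouse 3 for pericentral genes (7.04). Ethanol-fed vehicle mouse 5 stood apart for zinc, copper and manganese (5.48) and acute phase genes (7.17), and ethanol-fed vehicle mouse 3 for neutrophils (0.64).

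The PCB126 effect differed between diets by edgeR's interaction test for Tuba8 (-2.04, adjusted p = 2.73e-05), Maoa (1.53, 3.83e-05), Aldh3b1 (1.78, 0.00449), Ugt1a6b (-0.82, 0.0193) and Cyp3a11 (-1.48, 0.0453), each with n = 6 per group. Of lists, the lipid uptake median of -0.25 passed with a preset (adjusted p = 6.2e-05) and an estimated correlation (adjusted p = 0.0491). The other lists passed with the preset correlation alone: PPAR-alpha (-0.28, adjusted p = 1.41e-07), acute phase (-0.83, 8.93e-08), pericentral (-0.40, 0.00064), coagulation (-0.16, 0.00667), cytokines (0.86, 0.0144), lymphocytes (0.48, 0.00595), stellate cells and matrix (0.36, 0.000445), endothelium (0.23, 0.00964) and cholangiocytes (0.31, 0.0197). With an estimated correlation the adjusted p was 0.434 for PPAR-alpha, acute phase, pericentral and cholangiocyte genes, 0.742 for coagulation, cytokines and endothelium, 0.514 for lymphocytes and 0.517 for stellate cells.

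Of 100 library splits into groups of the same sizes (fixed seed), only the real one gave as many calls in each comparison. This argues against chance (1 in 100 at best), with too few interaction calls to judge. The real count and the highest other were 360 and 26 for PCB126 in pair-fed mice, 782 and 643 for PCB126 in ethanol-fed mice, 5044 and 2076 for ethanol in vehicle mice, 5579 and 2291 for ethanol in PCB126 mice, and 5 and 1 for the interaction. In each of the 4 simple comparisons, the highest other split exchanged 1 library per group with the real one.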

How the results depend on the processing

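Thinning every library to the total of the shallowest and leaving out the 3 libraries under 11 M (1e6) counts were chosen after seeing the data. The 5 counts of called genes and the 5 counts with at least a 2-fold change stayed within 1.5 times of their value with DESeq2 size factors, with the filter of 1 CPM in 6 libraries, with a replicate block and without robust estimation.

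For PCB126 in pair-fed mice, the count of 360 was about 2.1e+02 (140 up and 69 down) with no filter, 564 with DESeq2, 1093 with limma-voom weights and 179 with thinned libraries, and 79 genes changed at least 2-fold against 40 with thinned libraries. For PCB126 in ethanol-fed mice, 782 became 521 with no filter, 1189 with DESeq2, 491 with limma-voom weights, 270 with only the 2 groups compared, 400 with thinned libraries and 281 without the 3 shallow libraries. The 323 genes changed at least 2-fold there became 154 with limma-voom weights, 105 with only the 2 groups compared, 140 with thinned libraries and 118 without the 3 shallow libraries. With thinned libraries the at least 2-fold counts of ethanol, 1063 in vehicle and 1189 in PCB126 mice, became 642 and 725. The interaction's 5 genes became 53 with DESeq2 and 2 with thinned libraries, and its 4 genes of at least 2-fold became 31 and 2. The 3 shallow libraries are all ethanol-fed, so leaving them out keeps 6 against 6 pair-fed mice (391 genes) and leaves 4 against 5 ethanol-fed mice. The causes of these moves were not tested further.

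Leaving out 1 library at a time gave 163 to 443 genes for PCB126 in pair-fed mice (163 without vehicle mouse 3, 184 up and 32 down without vehicle mouse 5 and 227 without PCB126 mouse 3; at least 2-fold 54 to 84). In ethanol-fed mice it gave 333 to 1244 (403 and 481 without vehicle mouse 1 or 4, 440, 1244 and 333 without PCB126 mouse 1, 2 or 5). The at least 2-fold count there ranged from 143 to 462 (172 without vehicle mouse 1, 184 up and 20 down without vehicle mouse 4, 167 and 143 without PCB126 mouse 1 or 5). The ranges were 4463 to 5230 and 1008 to 1123 for ethanol in vehicle mice, 4947 to 5769 and 1112 to 1338 in PCB126 mice, and 3 to 11 and 3 to 8 for the interaction. The interaction's count was 3 without pair-fed vehicle mouse 6, pair-fed PCB126 mouse 1 or ethanol-fed vehicle mouse 2, 8 without ethanol-fed vehicle mouse 3 and 11 without ethanol-fed PCB126 mouse 2.

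Of gene lists, camera called 10, 16, 18, 19 and 12 in the 5 comparisons with the preset correlation and 1, 1, 0, 0 and 1 with an estimated correlation, which allows for genes that vary together. Over all lists and comparisons, 72 calls were lost and 93 results kept their side of the threshold. Among genes named in the text, 3 results that passed no threshold turned in sign. Tiparp with PCB126 in pair-fed mice (0.18) was -0.0188 with limma-voom weights and -0.19 without PCB126 mouse 5 (range without 1 library -0.19 to 0.30). Cyp1a1 with ethanol in vehicle mice (-0.06) was 0.37 with limma-voom weights, 0.0466 with a replicate block, 0.0309 and 0.43 without pair-fed mouse 5 or 6 and 0.0306 without ethanol-fed mouse 3 (range without 1 library -0.18 to 0.43). Cyp1b1 with ethanol in PCB126 mice (-0.36) was 0.0333 without pair-fed mouse 5 (range without 1 library -0.69 to 0.0333), and the cause was not tested.

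Among the other results on named genes, 376 of the fits without 1 library lost a call and 11 gained one, while 9208 kept their side. With no filter 38 named calls were lost, with only the 2 groups compared 40, without the 3 shallow libraries 41 and with thinned libraries 29. The replicate numbers do not pair mice across groups: over 36 pairs with the same number the mean correlation was -0.02, 6 pairs exceeded 0.1, and 6 of 24 libraries correlated best with their own number. With a block for the number the counts were 310, 545, 4792, 5310 and 4. The shallowest library held 5.39 M counts, 19.1-fold less than the deepest, and with library totals made equal 179, 400 and 2 genes passed for PCB126 in pair-fed mice, PCB126 in ethanol-fed mice and the interaction.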

Other observations

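Leaving out the 3 shallow libraries was chosen after seeing the data, and the other tests in this part were planned.

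Ethanol moved clock, coagulation and further cell type genes in vehicle mice. Of 19 circadian genes, 11 fell and 4 rose (the same counts adjusted over the list alone), with Usp2 (-1.87 ± 0.23, log2 ± SE, n = 6), Tef (-1.17 ± 0.16) and Hlf (-0.87 ± 0.11), output genes of the clock, down. Of 27 coagulation and complement genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone), including complement C9 (-1.19 ± 0.15), prekallikrein Klkb1 (-0.99 ± 0.13) and F11 (-0.83 ± 0.17). Of 6 erythroid genes, 3 fell by either adjustment, with the erythroid heme synthesis enzyme Alas2 (-1.33 ± 0.13) and Klf1 (-1.49 ± 0.34). Camera called these 3 lists down (adjusted p = 0.0112, 0.00245 and 0.00245), and the adjusted p = 0.417, 0.587 and 0.417 with an estimated correlation. Camera did not call the others. Of 15 endothelial genes, 3 rose and 3 fell (also 3 and 3 adjusted over the list alone), with Lyve1 up (1.78 ± 0.26) and Dnase1l3 down (-0.60 ± 0.11), and of 10 cholangiocyte genes 3 rose by either adjustment, with Krt23 (3.36 ± 0.36) and Sox9 (1.49 ± 0.27). Of 5 adipocyte genes, 1 rose (Fabp4, 0.60 ± 0.16) and 2 fell (Cfd, -3.16 ± 0.74, and Adrb3, -1.06 ± 0.31), with the same counts adjusted over the list alone. Cela1 (-0.63 ± 0.14), the pancreatic acinar gene tested, and mt-Nd6 (-0.93 ± 0.25), 1 of 7 mitochondrial genes, fell. Median and mean differed in sign for endothelial, cholangiocyte and mitochondrial genes. Without 1 library the circadian genes that rose became 2 (pair-fed mouse 3), the coagulation genes that fell 14 (ethanol-fed PCB126 mouse 1 or 5) and the erythroid genes that fell 6 (ethanol-fed mouse 6). With no filter 2 circadian genes rose, with DESeq2 or only the 2 groups compared 14 coagulation genes fell, and 5 erythroid genes fell with limma-voom weights and 6 without the 3 shallow libraries.

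In PCB126 mice, ethanol lowered 8 of 19 circadian genes and raised 3 (10 and 3 adjusted over the list alone), with Usp2 at -1.36 ± 0.22, and lowered 19 of 27 coagulation genes and raised 1 (20 and 1 adjusted over the list alone), with C9 at -1.07 ± 0.15. With only the 2 groups compared 12 coagulation genes fell, and 11 without the 3 shallow libraries. Of 6 erythroid genes 3 fell (also 3 adjusted over the list alone; Alas2 -1.96 ± 0.13) and of 10 cholangiocyte genes 4 rose (also 4 adjusted over the list alone; Krt23 3.70 ± 0.36). Camera called these 4 lists (adjusted p = 0.0375, 2.66e-06, 0.0174 and 0.0174), and each had an adjusted p = 0.393 with an estimated correlation. Of 15 endothelial genes 4 rose and 1 fell (the same adjusted over the list alone; Lyve1 2.01 ± 0.26), and of 5 adipocyte genes 1 rose and 3 fell (the same adjusted over the list alone; Adrb3 -1.10 ± 0.30), without a camera call. Cela1 fell (-0.55 ± 0.15), as did mt-Nd6 (-0.64 ± 0.24; edgeR adjusted p = 0.129 without pair-fed mouse 4), whose call was lost adjusted over the list alone and whose list had 1 gene at an unadjusted p under 0.05 and 1 called by DESeq2. The share of albumin counts was 8.13% in pair-fed and 7.39% in ethanol-fed PCB126 mice.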
